A study of Saccharomyces cerevisiae with 4 samples.

How the data were processed

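Messenger RNA of yeast was measured by RNA sequencing in 4 libraries: 2 of a wild-type strain and 2 of an xpo1-1 mex67-5 strain, all after 1 h at 37 °C. Total RNA was selected for poly(A) and made into libraries with a kit that does not mark the strand, and read as single 50 bp reads, per the labels' protocols. The authors deposited whole-number counts of reads per gene and, separately, counts of reads per intron for each library. The submitters' processing notes name bcl2fastq 2.17, STAR 2.5, featureCounts, DESeq2 1.8.2 and yeast build R64, without the role of each. How reads in several places, overlapping genes or intron edges were counted is not given in the sources used here. Reads of a gene and of an antisense or overlapping partner cannot be told apart without strand, and reads shared by near-identical paralogs or repeats may be split between them.

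The gene files list 7126 features, of which 6162 matched the RefSeq annotation of build R64 by name and 964 did not; 299 had 0 reads in all libraries. The intron files list 358 records by gene, number and start. Start positions matched exon gaps of the RefSeq annotation, which gave the ends. Records on 7 nuclear chromosomes (166) and the mitochondrial records (31) held 0 reads in every library and were treated as not counted, which leaves 161 records on 9 chromosomes. Of these, 135 have a RefSeq end and 26 do not. The number of unused columns of per-sample values was 0.

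Groups came from the genotype in the labels. Replicates of a group differed by more than sampling noise (chi-square per degree of freedom 10.6 for genes in the wild type and 7.15 in the mutant). Each library was therefore treated as 1 sample, although that spread may be technical and does not show separate cultures. The biological coefficient of variation was 2.95%. At this depth, a group's floor was set at 3 counts over the group.

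Genes were tested with edgeR 4.0.16 (R 4.3.3): filterByExpr, TMM scaling (factors 0.994, 0.999, 1.01 and 0.996), robust quasi-likelihood fits and F-tests, two-sided, with Benjamini-Hochberg adjustment at 0.05 and a model of group alone. CPM are reads per 1000000 of the scaled library size. Intron-to-gene ratios were tested in the same way as the interaction of feature (intron or gene) and group in 1 model over both kinds of count, with a term per library and the same library size for both; introns needed 10 reads over the 4 libraries and a gene past the filter. Of the tested introns, 5 lack a RefSeq intron. Intron abundance used the gene library sizes. The ratio of ribosomal protein introns to others used 100000 permutations, and shares used exact permutation.

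Before the data were examined, 29 gene lists, 5 classes of introns, the tests, the alternatives and the rule for named genes were fixed. Lists with at least 5 tested genes entered limma 3.58.1 camera on log2 CPM (prior count 2, preset correlation 0.01), Benjamini-Hochberg over 28 lists; camera with an estimated correlation and fry were alternatives. The list of the 2 mutated receptor genes was too small for camera (1 rose, 1 fell, 2 adjusted over the list alone). Named genes were CRM1 and MEX67, the 5 largest rises and 5 largest falls among called genes with a mean log2 CPM of at least 3 and no overlap between groups, and the 2 (4 for some lists) members of each list with the smallest adjusted p. Other members named were chosen after their values were seen: HSP10, AHA1, RPL15B, the few members of a list that went against the rest, the introns of RPS18A, RPS24A, GLC7 and UBC4, and the genes of the closing section. Named introns were the 6 largest rises and 4 largest falls with at least 20 reads on average in a group, a fixed set of well-studied introns, and 2 per class.

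The steps were first tested on simulated counts with the real means and library sizes. Dispersions were those estimated for genes, but a single assumed value for introns and the genes paired with them. At each fold 50 genes or 10 introns were changed, fewer than in the data, and genes were drawn independently. The rates below therefore need not hold for these data. For genes (6531 tested), 84% of those changed 1.2-fold, 92% at 1.5-fold and 98% at 2-fold were recovered, with 14 false calls. For intron ratios (135 tested), 40% at 1.2-fold, 90% at 1.5-fold and 100% at 2-fold were recovered, with 2 false calls. For intron abundance (135 tested), 50% at 1.2-fold, 90% at 1.5-fold and 100% at 2-fold were recovered, with 1 false call. A list of 40 genes raised 2-fold gave a camera p of 4.1e-81, and an unshifted list 0.364.

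Alternatives were other scalings, DESeq2 1.42.0, a replicate block, other filters and thresholds, other sets of introns, and leaving out each library in turn. Figures were drawn with matplotlib 3.10.9.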

Results

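Polyadenylated RNA of the budding yeast Saccharomyces cerevisiae was sequenced from a wild-type strain (n = 2 libraries) and from a strain with mutations in both Xpo1 and Mex67 (xpo1-1 mex67-5, n = 2 libraries). Xpo1, encoded by CRM1, is a nuclear export receptor of the karyopherin family, and Mex67 is the main export receptor of messenger RNA. Cells grew overnight at 25 °C and were shifted to 37 °C for 1 h before harvest. The study set out to compare splicing between both strains. The wild-type libraries held 49865570 and 49321384 reads assigned to genes, and the mutant libraries 62205252 and 50843634. Reads assigned to introns numbered 180810 and 175947 in the wild type, against 94133 and 75902 in the mutant. Nothing in the labels says that libraries of a group came from separate cultures, so p-values measure the spread between these libraries, which may be technical.

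The first comparison asked how messenger RNA levels of the mutant differed from the wild type after the shift. Of the genes that carry the mutations, MEX67 (YPL169C, chromosome XVI, 229039 to 230838) was 12.5-fold higher in the mutant, at 1925 ± 30.9 reads per 1000000 scaled reads (CPM; SD, n = 2) against 154 ± 3.25. CRM1 (YGR218W, chromosome VII, 932541 to 935795) was slightly lower, at 189 ± 1.94 CPM against 219 ± 2.57, a log2 change of -0.21 (SE 0.03). The edgeR quasi-likelihood adjusted p (Benjamini-Hochberg) was 4.3e-21 for MEX67 and 1.4e-05 for CRM1. Neither value tests the genotype, because a temperature-sensitive allele is still transcribed.

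In the mutant, genes for cytosolic ribosomal proteins and ribosome assembly were low and most heat shock genes high. Of 6563 genes tested, 3070 were higher and 3039 lower at an edgeR quasi-likelihood adjusted p (Benjamini-Hochberg) under 0.05, and 454 were not called. A change of at least 1 on the log2 scale was found in 1823 genes that rose and 1675 that fell. The libraries of both groups did not overlap in 6330 genes, where chance alone gives 33.3%. The median log2 change over all genes was 0.01. These are changes of share within a library, so a change in total messenger RNA per cell would not be seen.

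Among well-expressed genes the largest rises included HSP30, a plasma membrane heat shock protein (chromosome III, 156109 to 157107), which went from 25.8 ± 1.33 to 12586 ± 1042 CPM, a 488-fold rise. YHR054C rose 526-fold, from 1.44 ± 0.223 to 756 ± 11.95 CPM; it lies in the repeated CUP1 region, so its reads may be split among copies. YBR072C-A, a small open reading frame next to HSP26, rose 441-fold. HIS3, a histidine synthesis enzyme used as a selection marker, had 10 and 8 reads in the wild type against 20902 and 17918 in the mutant, and the subtelomeric YFR057W had 1 and 0 reads against 3108 and 2413. For YFR057W the ratio of reads was 4806, with an exact 95% counting interval of 862 to 189876, and its log2 change of 11.93 became 14.36 without wild-type replicate 1, which leaves 0 wild-type reads, and 11.07 without replicate 2. The largest falls were in the Ty element open reading frame YLR227W-B, with 889 and 915 reads in the wild type and 0 and 1 in the mutant, a ratio of 2072 with a counting interval of 371 to 81893; its log2 change of -10.68 became -9.68 without mutant replicate 1 and -12.94 without mutant replicate 2. AIF1, a mitochondrial cell death effector, fell from 53.2 ± 0.273 to 0.0356 ± 0.00545 CPM, YBR013C fell 453-fold, RPL8A, a large-subunit ribosomal protein gene, 265-fold, and ASC1, a ribosome-bound scaffold protein whose intron holds SNR24, 68.0-fold. The edgeR quasi-likelihood adjusted p (Benjamini-Hochberg) was at most 3.7e-17 for each of these 10 genes. Ty elements and subtelomeric genes have near-identical copies, and how their shared reads were counted is not given in the sources used here.

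Genes for cytosolic ribosomal proteins fell without exception, and ribosome assembly genes fell nearly as a whole. All 138 ribosomal protein genes measured were lower, with a median log2 change of -4.09, which is 17.1-fold. RPL2A fell 49.8-fold, RPL14A 42.6-fold and RPS10B 57.7-fold, and the smallest change was in RPL15B (log2 -0.28). Adjusted over the list alone, 138 were called. Camera gave an adjusted p of 4.8e-23, with adjusted p = 0.339 with an estimated correlation. Of 70 ribosome biogenesis factors, 69 fell and 1, UTP20 (log2 0.16), rose (70 adjusted over the list alone), with a median of -2.12. RRB1, which chaperones a ribosomal protein, fell 10.9-fold and NOP7, a factor of the large subunit, 10.8-fold. In camera, the adjusted p was 1.0e-12, with adjusted p = 0.422 with an estimated correlation. Mitochondrial ribosomal proteins were less affected, with 39 of 56 lower and 12 higher (51 adjusted over the list alone), a median of -0.50 and a camera adjusted p of 0.00826, with adjusted p = 0.441 with an estimated correlation. MRPS16 fell 3.95-fold. MRP8, which rose 3.32-fold, matched that list by name only; without it, an alternative chosen after seeing the data, 39 fell and 11 rose.

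Chaperone and stress genes rose. Of 25 heat shock genes controlled by Hsf1, the heat shock transcription factor, 22 rose and 2 fell (24 adjusted over the list alone), with a median log2 change of 3.06. BTN2 rose 229-fold, from 44.4 ± 2.22 to 10184 ± 344 CPM, the Hsp70 gene SSA4 rose 62.9-fold, the small heat shock protein gene HSP26 55.0-fold and FES1, an Hsp70 exchange factor, 18.7-fold. HSP10 (log2 -0.33) and AHA1 (-0.17) fell. The camera adjusted p was 7.2e-06, with adjusted p = 0.441 with an estimated correlation. Of 30 genes of the general stress response driven by Msn2 and Msn4, 27 rose and 3, GRX1, SOD2 and YGP1, fell (30 adjusted over the list alone), with a median of 2.61. GAC1, a phosphatase subunit, rose 34.7-fold and the aldehyde dehydrogenase gene ALD3 21.7-fold. The camera adjusted p for this list was also 7.2e-06, with adjusted p = 0.384 with an estimated correlation. Both strains received the same shift, so the differences are between strains at 37 °C.

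**Figure D1:**
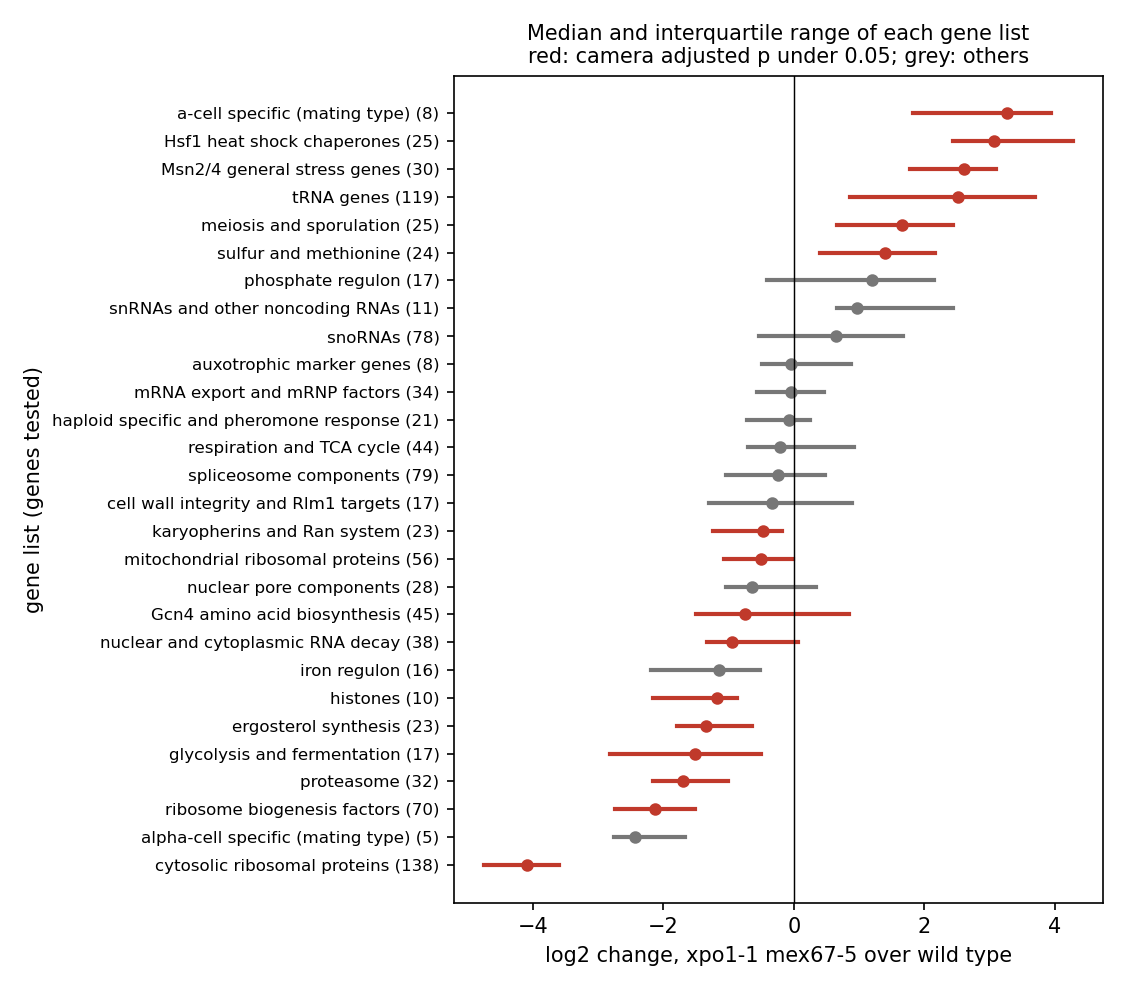
Median log2 change (points) and interquartile range (bars) of the genes in each list, mutant over wild type, with the number of genes tested in brackets. Cytosolic ribosomal proteins lie lowest at a median of -4.09, and the a-cell genes highest at 3.26.

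Several metabolic and protein turnover groups fell. Proteasome genes were lower in 29 of 32, with a median log2 change of -1.70 (31 adjusted over the list alone): PRE3, a core subunit, fell 12.6-fold, while RPN4, the transcription factor that drives proteasome genes, rose 42.9-fold and RPN1 also rose (log2 0.67). Camera gave an adjusted p of 1.0e-05, with adjusted p = 0.339 with an estimated correlation. All 23 ergosterol synthesis genes fell (23 adjusted over the list alone), with a median of -1.34, ERG3 by 8.60-fold and ERG4 by 5.01-fold, at a camera adjusted p of 1.0e-05, with adjusted p = 0.339 with an estimated correlation. Glycolysis and fermentation genes fell in 14 of 17 and rose in 2 (16 adjusted over the list alone), with a median of -1.52. TPI1, triose phosphate isomerase, fell 10.2-fold, and PDC5, a pyruvate decarboxylase, rose 8.33-fold, as did HXK2 (log2 0.19) to a small extent. In camera, the adjusted p was 0.00568, with adjusted p = 0.503 with an estimated correlation. Of 45 Gcn4-controlled amino acid synthesis genes, 31 fell and 12 rose (43 adjusted over the list alone), with a median of -0.74, and the lysine synthesis gene LYS12 fell 15.7-fold. For these 45, the camera adjusted p was 0.0410, with adjusted p = 0.503 with an estimated correlation. HIS3 is a member too; without the markers HIS3, LEU2 and LYS2, an alternative chosen after seeing the data, 30 of 42 fell, with a median of -0.79 and a camera adjusted p of 0.0168 (adjusted p = 0.478 with an estimated correlation). Histone genes fell in 8 of 10 and rose in HHT1 and HTA1 (10 adjusted over the list alone), with a median of -1.18, HTA2 by 8.36-fold and HHO1 by 6.32-fold, at a camera adjusted p of 0.0430, with adjusted p = 0.503 with an estimated correlation.

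Sulfur and meiotic genes rose, as did the pooled reads of transfer RNA genes. In the sulfur and methionine list 20 of 24 rose and 4, CYS4, MET22, SAM1 and CYC3, fell (24 adjusted over the list alone), with a median log2 change of 1.40. CYC3 encodes cytochrome c heme lyase and was put in that list in error; without it, an alternative chosen after seeing the data, 20 rose and 3 fell, with a median of 1.54 and a camera adjusted p of 0.00137 (adjusted p = 0.359 with an estimated correlation). The amino acid transporter gene MUP3 rose 15.1-fold and STR3, of cysteine to methionine conversion, 11.3-fold. For the full list, camera gave an adjusted p of 0.00304, with adjusted p = 0.384 with an estimated correlation. Of 25 meiosis and sporulation genes, 23 rose and 1, PCH2, fell (24 adjusted over the list alone), with a median of 1.66. SPO11, which makes meiotic DNA breaks, rose from 8.48 ± 0.294 to 98.2 ± 2.68 CPM, and SPO1 rose 6.88-fold. In camera, the adjusted p was 6.6e-05, with adjusted p = 0.339 with an estimated correlation. Of 299 transfer RNA genes 119 passed the count filter, and of these 89 rose and 12 fell (101 adjusted over the list alone), with a median of 2.51 that was unaltered when the 5 genes without wild-type reads were put at their bound. The median level was only 0.404 CPM in the mutant, so these are few reads, and many genes passed the filter through their mutant reads. Pooled over all 299, reads went from 34.9 ± 0.437 to 114 ± 4.53 CPM, 3.28-fold higher, and over the 180 that were not tested 2.66-fold higher. Of the 29 with at least 10 reads in both wild-type libraries, a cut chosen after seeing the data, 8 rose and 12 fell, with a median of 0.21, so the rise is not one of every transfer RNA gene. Both tS(AGA)J, 103-fold, and tM(CAU)O2, 54.8-fold, rose, on few wild-type reads. The first had 2 and 4 reads in the wild type against 413 and 322 in the mutant. The second had 8 and 5 against 462 and 371. The RNA was selected for poly(A) and strand was not marked, so which transcripts gave the reads of transfer RNA genes is not known. The camera adjusted p was 1.0e-05, with adjusted p = 0.339 with an estimated correlation.

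Genes of RNA export, transport and decay went in both directions. In the mRNA export list 14 of 34 rose and 15 fell (29 adjusted over the list alone), with a median log2 change of -0.04 and a camera adjusted p of 0.763 downward, while fry put the list upward without passing (adjusted p = 0.139). Apart from MEX67, HRP1, an RNA-binding shuttling protein, rose 4.74-fold, while NPL3, a shuttling adaptor of export, fell 10.8-fold and PAB1, the poly(A)-binding protein, 6.54-fold. Karyopherins and the Ran system fell in 19 of 23 and rose in CSE1, KAP120, MTR10 and GSP2 (23 adjusted over the list alone), with a median of -0.47. The import receptor gene KAP123 fell 5.90-fold and RNA1, the Ran GTPase activator, 5.91-fold. Camera gave an adjusted p of 0.00940, with adjusted p = 0.339 with an estimated correlation. RNA decay genes fell in 27 of 38 and rose in 8 (35 adjusted over the list alone), with a median of -0.94. The exonuclease gene XRN1 fell 3.77-fold and DCP1, of the decapping enzyme, rose 5.42-fold. In camera, the adjusted p was 0.0219, with adjusted p = 0.339 with an estimated correlation. Nuclear pore genes fell in 20 of 28 and rose in 8 (28 adjusted over the list alone), at a camera adjusted p of 0.0697, with NIC96 up 4.63-fold and ASM4 up 4.02-fold.

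Spliceosome genes went in both directions. Of 79 components, 44 fell and 27 rose (71 adjusted over the list alone), with a median log2 change of -0.24, a camera adjusted p of 0.236 and a fry adjusted p of 0.00304 downward. MUD1, of the U1 particle, rose 8.67-fold and the second-step factor PRP18 6.82-fold, while SNU13 fell 4.62-fold and the disassembly helicase PRP43 4.90-fold. Of 11 small nuclear and other noncoding RNAs, 8 rose and 1 fell (9 adjusted over the list alone), with a median of 0.97. SCR1, the signal recognition particle RNA, rose 16.8-fold, RPR1, the RNase P RNA, 9.45-fold and NME1, the RNase MRP RNA, 3.08-fold, while TLC1, the telomerase RNA, fell 6.15-fold. The camera adjusted p was 0.0601, and it passed 0.05 without wild-type replicate 1 (0.0415), wild-type replicate 2 (0.0229) or mutant replicate 1 (0.04998), and by fry (adjusted p = 0.00726). Small nucleolar RNAs rose in 42 of 78 and fell in 23 (65 adjusted over the list alone), with a camera adjusted p of 0.118. SNR47 rose 27.0-fold and SNR44 fell 8.29-fold. SNR44 lies in an intron of RPS22B. Most of these RNAs lack a poly(A) tail when mature, so selection for poly(A) sets which of their forms are read.

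Some genes that mark the mating type, and some selection markers, also differed between the groups, where 93.1% of all genes tested were called. Of these lists only that of a-cell genes passed camera. All 8 genes specific to a-cells rose (8 adjusted over the list alone), with a median log2 change of 3.26: MFA2, which encodes a-factor, went from 1.12 ± 0.0764 to 64.2 ± 1.86 CPM, and BAR1, the protease that degrades alpha-factor, rose 12.9-fold. Camera gave an adjusted p of 0.00311, with adjusted p = 0.339 with an estimated correlation. Of 5 genes specific to alpha-cells, 4 fell and 1, AFB1 (log2 1.07), rose (5 adjusted over the list alone), with a median of -2.43 and a camera adjusted p of 0.120. The pheromone gene MF(ALPHA)1 went from 1029 ± 13.4 to 44.7 ± 1.16 CPM, and the agglutinin gene SAG1 fell 6.78-fold. Haploid-specific and pheromone response genes rose in 8 of 21 and fell in 10 (17 adjusted over the list alone), with a median of -0.08 and a camera adjusted p of 0.611. SST2 fell 4.20-fold and FIG2 rose 3.78-fold. Of 8 auxotrophic marker genes, 3 (HIS3, LEU2, MET17) rose and 4 (ADE2, URA3, LYS2, CAN1) fell (7 adjusted over the list alone), with a median of -0.04, a mean of 1.36 and a camera adjusted p of 0.968 upward. HIS3 is given above, and LEU2 rose 5.22-fold. The labels name neither the mating type nor the markers of the strains, and every difference between groups is one between these strains.

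The remaining lists did not pass the list test. Respiration genes rose in 18 of 44 and fell in 24 (42 adjusted over the list alone), with a median of -0.21, a mean of 0.20 and a camera adjusted p of 0.747 downward. CIT1, citrate synthase, rose 6.26-fold and ATP17 fell 3.60-fold. Phosphate regulon genes rose in 11 of 17 and fell in PHO84, PHO86, VTC1, VTC2 and VTC4 (16 adjusted over the list alone; camera adjusted p = 0.122), with PHM8 up 9.79-fold and PHM7 up 13.3-fold. Iron regulon genes fell in 10 of 16 and rose in 1 (10 adjusted over the list alone), at a camera adjusted p of 0.0721 that passed 0.05 without wild-type replicate 1 (0.0215) or 2 (0.00510). CTH1 rose 4.87-fold and FRE1 fell 2.18-fold. Cell wall integrity genes rose in 8 of 17 and fell in 9 (17 adjusted over the list alone; camera adjusted p = 0.754), with PIR3 up 26.5-fold and CIS3 down 46.4-fold.

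In all, 16 of 28 lists passed camera with a preset correlation of 0.01, 6 upward and 10 downward. With an estimated correlation 0 passed, and 2 had an unadjusted camera p under 0.05. That version has few degrees of freedom with 2 libraries a group, so it could hardly pass any list. Calls were lost even where the estimated correlation lay under the preset, as for a-cell (-0.09) and meiosis (-0.04) genes. Its values therefore do not show that correlation between genes removes a call. Nor do they show that correlation removes none, because for some other lists the estimate lay far above the preset. It was 0.53 for glycolysis, 0.46 for Hsf1, 0.39 for ribosome biogenesis and 0.37 for histone genes. By fry, which asks whether the members of a list move 1 way on balance, 26 passed.

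The second comparison addressed splicing, through reads in introns relative to reads of the same gene. Gene reads and intron reads are separate counts, so the ratio can pass 100 intron reads per 100 gene reads. Introns gained on their genes in the mutant. Of 135 introns in 132 genes, 106 had a higher intron-to-gene ratio and 11 a lower ratio at an edgeR quasi-likelihood adjusted p (Benjamini-Hochberg) under 0.05, and 18 were not called. The median ratio was 4.34 intron reads per 100 gene reads in the wild type and 9.49 in the mutant, and the median log2 change of the ratio was 1.03 (2.04-fold). The intron of DTD1, a D-aminoacyl-tRNA deacylase (chromosome IV, 65307 to 65377), went from 1.03 ± 0.128 to 17.6 ± 0.866 intron reads per 100 gene reads, and that of SNC1, a vesicle fusion protein (chromosome I, 87388 to 87500), from 2.15 ± 0.0492 to 17.5 ± 0.827. The coordinates are those of build R64. Introns were measured on 9 of the 16 nuclear chromosomes, because the 166 intron records of the other 7 held 0 reads in every library although 156 of their 160 genes had reads.

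**Figure D2:**
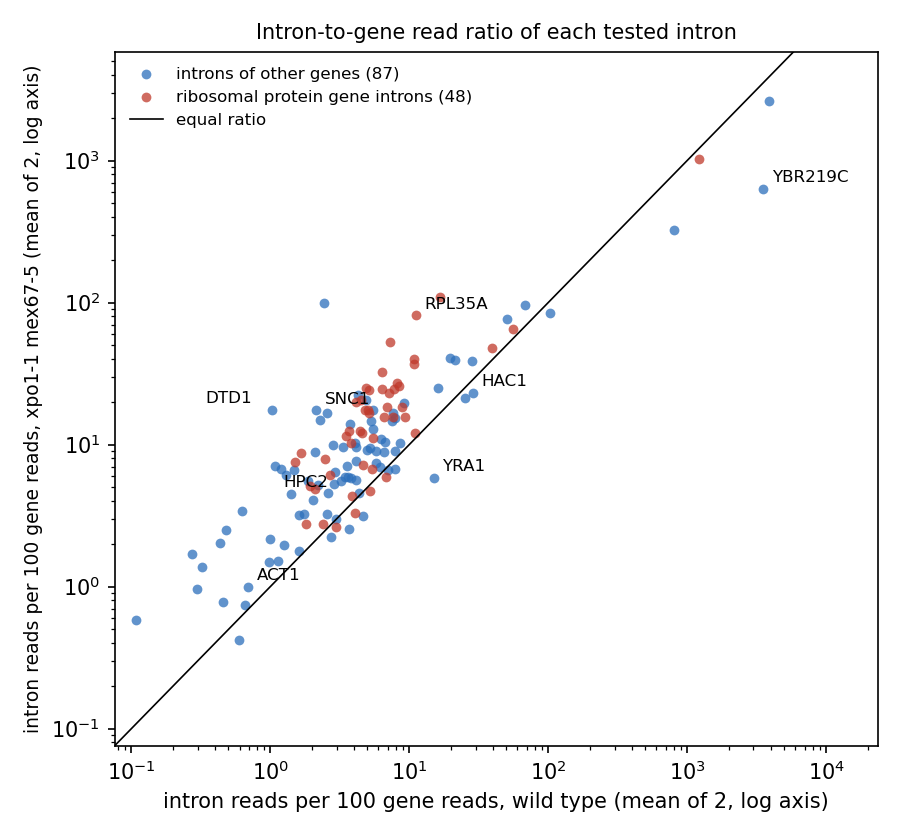
Intron reads per 100 gene reads of each of the 135 tested introns, mean of 2 wild-type libraries (horizontal, log axis) against mean of 2 mutant libraries (vertical, log axis); red points are introns of ribosomal protein genes and blue points those of other genes. Most points lie above the line of equal ratio, and YRA1, HAC1 and YBR219C lie below it.

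Among the introns with the largest rise were those of 3 ribosomal protein genes, RPL35A (7.32-fold; chromosome IV, 117667 to 118157), RPL43B (7.26-fold; chromosome X, 608307 to 608581) and RPL35B (6.62-fold; chromosome IV, 217603 to 218007). The RPL35A intron went from 11.2 ± 0.250 to 81.8 ± 7.30 reads per 100 gene reads, while its gene fell by 3.74 on the log2 scale. RPL35B went from 16.5 to 109 reads per 100 gene reads, with more intron reads in the mutant (1236 and 1080) than gene reads (1117 and 1002). The intron of HPC2, a histone regulator (chromosome II, 653369 to 653452), rose 6.55-fold relative to its gene and that of PFY1, profilin, 6.54-fold. In SUS1, a factor of mRNA export with 2 introns, both ratios rose, by 1.94-fold for intron 1 and 1.85-fold for intron 2. The ACT1 intron, of the actin gene (chromosome VI, 54378 to 54686), rose from 0.693 ± 0.0641 to 1.00 ± 0.0841 reads per 100 gene reads. The edgeR quasi-likelihood adjusted p (Benjamini-Hochberg) of these 8 introns was at most 9.9e-05. The introns of RPL30 and DBP2 lie on chromosomes whose records held 0 reads, and they and the MTR2 intron were not analysed here.

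The fall of the ratio in YRA1 was the clearest among the 11. YRA1, an mRNA export adaptor that limits its own level through its intron (chromosome IV, 1236843 to 1237608), went from 15.0 ± 0.347 to 5.85 ± 0.00844 intron reads per 100 gene reads, a 2.57-fold lower ratio, at an edgeR quasi-likelihood adjusted p (Benjamini-Hochberg) of 8.5e-12. Its gene reads rose by a log2 change of 1.15 and its intron reads fell by 0.21. The ratio also fell in YBR219C (5.13-fold), YBR090C (2.48-fold) and YJR079W (1.54-fold), but these records held more reads than their genes, and those of YBR219C and YJR079W overlap YBR220C and AIM24. The YBR219C gene had 11 and 7 reads in the wild type. HAC1, the unfolded protein response factor whose intron is removed outside the spliceosome, went from 29.0 ± 0.0877 to 23.2 ± 0.155 per 100 gene reads, with the intron up by a log2 change of 1.46 and the gene by 1.78. Without mutant replicate 1, 7 introns were lower in place of 11, and the YJR079W change shrank from a log2 of -0.62 to -0.30 and lost its call (edgeR quasi-likelihood adjusted p, Benjamini-Hochberg, 0.184). That call was also lost with the host gene count as offset (log2 -0.57, adjusted p 0.181) and without ribosomal protein introns (-0.62, 0.0667), where the change stayed near its size, each by edgeR quasi-likelihood with Benjamini-Hochberg adjustment.

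By class of gene, 14 of 19 regulated or well-studied introns rose relative to their gene and 4, YRA1, HAC1, GLC7 and UBC4, fell (18 adjusted over the list alone). Of 5 introns of meiotic genes, 3 rose and 0 fell at the adjusted threshold (3 adjusted over the list alone), among them MEI4 (2.30-fold), whose gene rose by a log2 change of 2.90, and SPO22 (4.69-fold, on 10 and 3 wild-type reads, with a log2 change of 2.23 that was 3.36 and 1.57 without wild-type replicates 1 and 2). Both introns that hold a small nucleolar RNA rose (2 adjusted over the list alone), TEF4 with SNR38 by 5.24-fold and EFB1 with SNR18 by 1.11-fold. The EFB1 call was lost without wild-type replicate 2 (log2 0.12) or either mutant replicate (0.19 and 0.12).

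Intron reads themselves, without reference to the gene, rose in 43 of 136 introns and fell in 82 at an edgeR quasi-likelihood adjusted p (Benjamini-Hochberg) under 0.05. All 48 introns of ribosomal protein genes fell, with a median of 5.79-fold, less than the 16.6-fold fall of their genes. Of 87 introns of other genes, 43 rose and 34 fell. The DTD1 intron rose from 0.546 to 1.53 CPM while its gene fell, and the MEI4 intron rose from 0.546 to 9.43 CPM. Of the 106 introns whose ratio rose, 61 had fewer intron reads in the mutant and 36 had more, and 83 had a gene that fell.

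**Figure D3:**
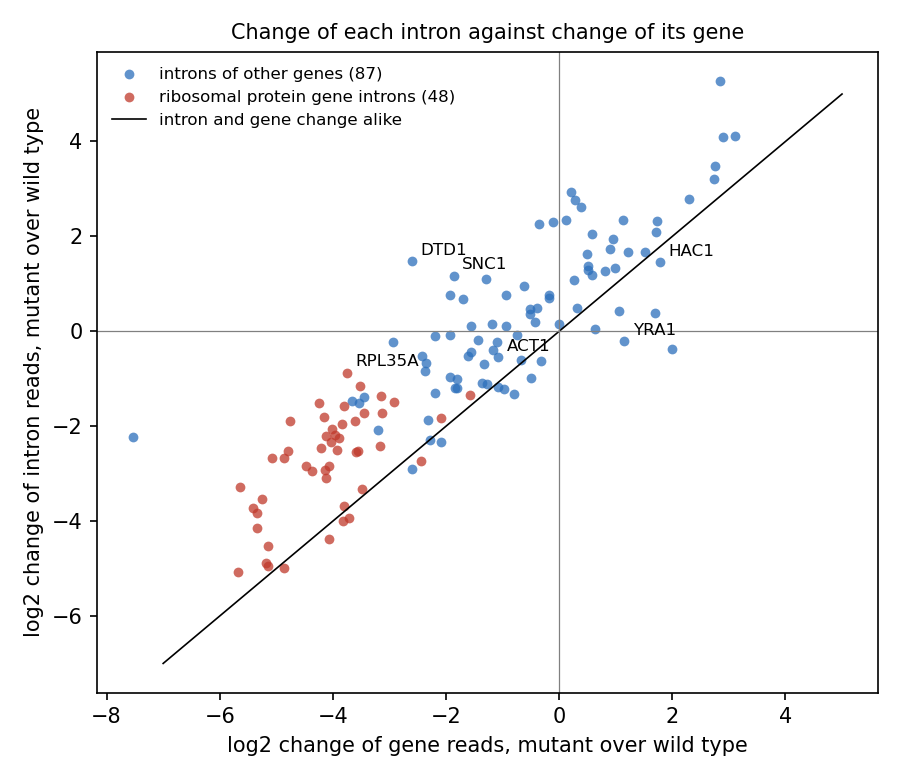
Log2 change of intron reads (vertical) against log2 change of gene reads (horizontal), mutant over wild type, for the 135 tested introns; the diagonal marks an equal change of both. All 48 ribosomal protein introns (red) lie below 0 on both axes, most of them above the diagonal, while 43 introns of other genes (blue) rose in abundance.

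Ribosomal protein introns rose more than other introns relative to their genes. In the ribosomal protein class 40 of 48 rose and 2, RPS18A and RPS24A, fell (42 adjusted over the list alone), with a median log2 change of the ratio of 1.47. In the other class 66 of 87 rose and 9 fell (75 adjusted over the list alone), with a median of 0.88. The medians differed by 0.59 (two-sided permutation p = 0.00843 over introns, which are not independent replicates). The difference of means, 0.32, did not pass (permutation p = 0.0985), nor did that of medians among introns whose gene was lower (0.50, permutation p = 0.0944), a test chosen after seeing the data.

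The share of reads in introns was taken over the 161 intron records on the 9 chromosomes with intron reads. It was lower in the mutant with all of these records and higher when ribosomal protein introns were left out. Introns took 0.358% ± 0.00411 of intron and gene reads in the wild type (n = 2) and 0.150% ± 0.00144 in the mutant (n = 2), 2.39-fold less. Per library the shares were 0.361% (exact 95% binomial interval 0.360 to 0.363) and 0.355% (0.354 to 0.357) in the wild type, and 0.151% (0.150 to 0.152) and 0.149% (0.148 to 0.150) in the mutant. Without ribosomal protein introns the direction turned, from 0.0591% ± 0.000739 to 0.0939% ± 0.000110. Without the HAC1 intron as well, an alternative chosen after seeing the data, the rise was smaller, from 0.0467% ± 0.000117 to 0.0595% ± 0.00127. All gene reads, including those of ribosomal protein genes and of the chromosomes without intron reads, stayed in the total. The values are therefore not the share of every yeast intron. The fall of those genes by itself raises the share of other introns, so these rises are not gains relative to the introns' own genes. The two-sided exact permutation p was 0.333, the smallest that 2 against 2 libraries allow, so this comparison cannot reach 0.05. Intervals cover counting error only.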

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

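Other settings left most counts within 1.5 times; the ones without HAC1, without introns overlapping another gene, with RefSeq introns only, without 4 sets of list members and with lower genes only were chosen after seeing the data. A change of at least 1 on the log2 scale cut genes from 6109 to 3498 and intron ratios from 117 to 73, and leaving out ribosomal protein introns left 74, by construction fewer introns. The mutant minus wild-type intron share of -0.208 percentage points turned to 0.0348 without ribosomal protein introns and to 0.0128 without these and HAC1, and moved to -0.199 without the 5 introns with most reads and to -0.230 without HAC1. Lists passing camera went from 16 to 0 with an estimated correlation and 26 by fry. The ribosomal protein difference weakened to 0.324 for means and 0.497 among introns of lower genes; the cause was not tested. Leaving out each library gave 5937 to 6063 genes, 109 to 119 intron ratios, 114 to 124 intron abundances, 16 to 18 lists, shares of -0.211 to -0.205 and class differences of 0.571 to 0.705; the lone library of a group was assumed to vary like the others. Replicate numbers did not pair the samples (correlation of deviations -0.03). With the replicate block the counts were 6109 genes, 119 intron ratios, 126 intron abundances and 17 lists (the small nuclear and other noncoding RNAs passed at a camera adjusted p of 0.0345), and the class difference 0.585. No gene call turned direction in any of these fits. Depth limits introns with few reads: 25 records fell under 10 reads.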

Other observations

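Some loci had almost no reads in a single strain. Read counts do not show whether the sequence of such a locus is present in both strains. With at most 20 reads in a group and at least 500 in the other, 23 genes were near absent in the wild type and 8 in the mutant. Near absent in the wild type were PAU8, PAU10, PAU13 and PAU15, of a family of cell wall genes near chromosome ends (PAU8 had 0 reads against 488 and 377, at least 251-fold higher with a floor of 3 counts over the group), HIS3, and YOR203W (14 reads against 4554). Near absent in the mutant were COS12 (259 and 283 reads against 0 and 0), YNR071C (525 and 505 against 1 and 0), AIF1, YBR013C and the Ty1 element YBR012W-B beside it on chromosome II (331 and 342 against 2 and 2).

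Genes around MEX67 and HIS3 were also higher, where 3070 of all 6563 genes tested were higher. Whether these neighbours exceed that share was not tested. On chromosome XVI, COX10 (224353 to 225741) rose 4.05-fold, OYE3 91.7-fold, DAP1 6.41-fold, MRX4 7.75-fold and REV3 (232593 to 237107) 1.83-fold. Around HIS3 on chromosome XV, MRM1 rose 2.44-fold and DED1 1.96-fold. Small nucleolar RNAs went both ways: SNR71 rose 21.5-fold, SNR76 on chromosome XIII fell 16.9-fold, and its neighbour SNR75 had 85 and 72 reads in the wild type against 10 and 2 in the mutant. Features outside RefSeq, apart from transfer RNAs, rose in 313 of 493 and fell in 91, at a median level of 1.11 CPM in the wild type and 2.37 in the mutant. At such levels the count filter can admit a feature through the reads of a single group. Reads of an overlapping gene cannot be told apart from those of the feature.

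Of the tests below, those of host gene loss, of a1 and alpha2, of the other mating type, of the alpha-cell list, of matching on wild-type level and of ranking by a group were chosen after the result was seen. The higher intron-to-gene ratio may come from retained introns, from an even background of reads, or from loss of exon reads alone. Loss of exon reads alone is argued against only for introns whose gene did not fall. Of these 33, 23 (69.7%) had a higher ratio, with a median log2 change of 0.61. Against that, 6 of the 32 whose gene rose had a lower ratio. Of the 102 whose gene fell, 83 had a higher ratio, with a larger median of 1.23. For those the test cannot decide, because loss of exon reads would itself raise the ratio. A background was tested by subtracting the read density of the lowest 10% of introns in each library; 75 of 103 introns called higher kept the call, and the median log2 change was 0.99. That is fewer than the 80 set in advance as excluding a background, so a background stays open for the pattern as a whole. The strain difference named in the labels stays open as untested.

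The rise of a-cell genes was unlikely to follow from their low level: their median of 3.26 lay at percentile 100 of 10000 random lists matched on mean expression, whose 99th percentile was 1.38, and at 99.9 when matched on wild-type CPM. For the 5 alpha-cell genes a general fall of strongly expressed genes stays open. Their median of -2.43 lay at percentile 0.510 of lists matched on mean expression, under the bound of 1. It lay at 2.24 of lists matched on wild-type CPM, above that bound. The random lists could draw ribosomal protein genes, which all fell. The matching therefore cannot separate a general fall of strongly expressed genes from the fall of that class. Joint a1 and alpha2 information in most cells would repress HO, RME1, STE4, STE5, STE18, GPA1 and FUS3, whose median log2 change was -0.27 (from -1.08 to 0.42). A mutant strain of the other mating type cannot be told apart from the groups. Such a strain was taken to give reads of HMRA1, the silent a copy, and alpha-cell genes below the wild-type a-cell median. HMRA1 had 0 reads in the wild type and 174 and 154 in the mutant. These counts do not show whether the silent copy itself was their source. Alpha-cell genes in the mutant stayed at a median of 44.7 CPM, between the a-cell medians of 8.60 in the wild type and 59.7 in the mutant. The labels give no mating type.

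Weakly expressed genes rose and strongly expressed genes fell: by wild-type level, the lowest 10% of 5841 protein-coding genes had a median log2 change of 1.72 and the highest 10% one of -1.85. The highest 10%, from 305 CPM in the wild type, held ribosomal protein genes such as RPL2A (1552 CPM) and RPL14A (906 CPM). No ranking left that class out, so how much of the fall it makes up was not tested. Counting noise is argued against, because ranking by wild-type replicate 1 and measuring against replicate 2 gave 1.62 in the lowest 10%. Reads from raised neighbours could add to the rise. The 228 genes of the lowest 10% with a raised, more strongly expressed RefSeq gene within 1000 bp had a median of 2.36. The 356 without such a neighbour still had a median of 1.32, so these neighbours alone do not account for the rise. Neighbours raised by a log2 change under 1, or outside RefSeq, were not covered. Ranking by a compared group stays open: ranked by the mean of all 4 libraries the gap was 44.9% as wide, with medians of 0.94 and -0.66, and the 10% bands between had medians from -0.30 to 0.02 with no steady fall. Whether this follows from the mutant receptors was not tested.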
